A study of Mus musculus with 9 samples.

How the data were processed

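Crypt epithelial cells sorted from the duodenum of infected mice were profiled by stranded mRNA sequencing, per the labels' protocols (TruSeq Stranded mRNA libraries from RNeasy Mini RNA). The libraries were grouped by the tissue named in the titles, 4 granuloma and 5 non-granuloma. The labels name 5 mice and a number per library but do not state that a number marks a mouse. The p-values therefore measure the spread between these libraries.

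Per the submitters' processing notes, reads were aligned with STAR 2.4.0j and compared with DESeq2. The notes name build GRCh38, a human build, while the gene IDs of the file are mouse. Of the 43629 rows, 42548 IDs (97.5%) matched the GENCODE M21 annotation of GRCm38, and 99.9% of the matched genes overlapped their GRCm38 position, so coordinates are given as the file has them. The counting tool, the annotation release and the test formula are not given in the sources used here. The authors' values per library are a signal, read counts divided by 1 size factor per library: with a tolerance of 1e-06, 100% of the values in each column were whole multiples of its smallest non-zero value. The authors' deposited fold (ratio) and log2 columns equal the ratio of group means, and their deposited p-value columns hold a raw and a Benjamini-Hochberg adjusted p over 25913 genes. The number of value columns that matched no sample was 0.

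The recovered reads per library ranged from 21212861 to 55324247, and 3 reads, the upper limit a count of 0 allows, corresponded to 0.0542 to 0.141 CPM. Such limits cover counting error only. Replicate libraries differed beyond sampling noise (chi-square per degree of freedom from 14.7 to 72.5), so none was treated as a duplicate.

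The test design fixed before the data were examined assumed counts and edgeR. Since the file holds normalised values, the fallback written there was used: limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) with group as the only term and Benjamini-Hochberg adjustment at 0.05. The level filter, a value of at least 10 in at least 4 libraries, was chosen after the file had been seen and before any fit. It kept 14927 genes. Fold changes on this scale understate changes of low genes. On simulated reads in which 200 genes were changed, tested over 14870 genes, limma-trend recovered 34.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 81.8% of those changed 4-fold, with 8 false calls among 131, and edgeR (4.0.16), over 14740 genes, recovered 32.8%, 68.7% and 81.8%, with 7 among 129.

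The 28 gene lists (18 crypt programs or cell types, 10 other cell types) were fixed before the data were examined, with knowledge of the study's theme. Lists with at least 3 tested genes were tested with camera (correlation 0.01, Benjamini-Hochberg over 25 lists), camera with an estimated correlation and fry, which tests whether a list's genes move one way. A score per library was compared by an exact two-sided permutation test over the 126 splits (smallest possible p 0.00794). The 124 named genes were the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM (recovered reads per total, scaled) and no overlap between groups (predicted genes and receptor segments skipped), a fixed set including Lgr5, Ly6a and Mki67, and per list up to 3 called and up to 2 abundant uncalled members. The results of some of these genes are not reported here.

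Numbers shared by both groups were checked for pairing. The deviations from the group means correlated by 0.177, 0.137, 0.256 and 0.557 between Gr_316, Gr_336, Gr_359 and Gr_372 and the same-numbered NonGr libraries. Each was over 0.1, so the numbers were taken to pair the libraries in the replicate block. The main fit and its list tests took the libraries as unpaired. However, Gr_316 correlated more with NonGr_336 (0.368), and Gr_336 more with NonGr_359 (0.191), than with the same-numbered library. For Gr_359 and Gr_372 the same-numbered library correlated most. The pairing rests on the data, and part of it may come from the split of Gr_372, NonGr_361 and NonGr_372 from the others. The alternatives were a pseudocount of 0.1, no filter, a filter at 5 CPM, the replicate block, the 8 matched libraries without it, edgeR on the recovered reads with RLE factors or no scaling, DESeq2 (1.42.0), limma-voom and leaving out each library. Chosen after seeing the data were edgeR with TMM (with and without the block), a term for the set Gr_372, NonGr_361 and NonGr_372, this set and the other 6 libraries each alone, the mean Muc6 and Tff2 level as a covariate and the non-granuloma libraries with Muc6 alone. On the recovered reads, edgeR with TMM called 1332 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.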

Results

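RNA sequencing was used to compare crypt epithelial cells of the mouse duodenum next to, and away from, the tissue nodules (granulomas) that form around larvae of the roundworm Heligmosomoides polygyrus. Wild-type C57BL/6J mice had received about 200 infective (L3) larvae, and tissue was taken on day 6 of infection. Punch biopsies of 1 mm were pooled by tissue type, and live cells positive for EpCAM (an epithelial surface protein) and CD44 (a crypt marker) and negative for CD45 (a leukocyte marker) were sorted. The 9 libraries comprised 4 from granuloma tissue (named Gr_316, Gr_336, Gr_359 and Gr_372 in the labels) and 5 from non-granuloma tissue (NonGr_316, NonGr_336, NonGr_359, NonGr_361 and NonGr_372). The reads recovered from the deposited values numbered 21212861 to 28853412 per granuloma library and 21734689 to 55324247 per non-granuloma library. Levels below are normalised read counts, given as mean ± SD with n = 4 granuloma and n = 5 non-granuloma libraries, and fold changes are on the log2(value + 1) scale.

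The comparison asked how the transcriptome of crypt cells differs at the granuloma, and the series title concerns the intestinal stem cell program. Of 14927 genes tested, 652 were higher and 726 lower in granuloma libraries (limma-trend, Benjamini-Hochberg adjusted p below 0.05), of which 193 and 260 changed by more than 2-fold. Interferon-response and antigen-presentation genes were higher at the granuloma, together with the fetal-type surface gene Ly6a and the type 2 response gene Retnlb, which encodes a secreted goblet cell protein. Lgr5 and other crypt stem cell genes, Paneth cell defensins, tuft cell genes and absorptive enterocyte genes were lower. Of the tested members, 20 of 26 interferon-gamma response, 20 of 25 type I interferon response and 15 of 18 antigen presentation genes rose, and 8 of 23 stem cell, 9 of 13 Paneth cell, 4 of 13 tuft cell and 12 of 20 enterocyte genes fell, while none of these 7 list calls held with an estimated correlation (adjusted p from 0.0607 to 0.299). Each of these 7 lists passed fry (adjusted p from 0.000445 to 0.0446) and an exact permutation test of library scores that takes the libraries as unpaired (adjusted p from 0.022 to 0.0496). Over the 25 lists tested, 13 passed camera and 0 passed it with an estimated correlation. With fry, 12 passed (those of camera without the stress list). In the exact test, 12 passed (those of camera without the stress and Brunner gland lists and with the cell cycle list). Among called genes with a mean of at least 5 CPM and no overlap between the groups, predicted genes left out, the largest rises were in Lrg1 (a secreted glycoprotein; 461 ± 201 against 36.5 ± 35.1, adjusted p = 0.00145), Ly6a, Ido1 (a tryptophan-degrading enzyme), Anxa10, Hspa1a, Iigp1, Arl5c and Retnlb, with log2 changes of 4.01, 3.58, 3.24, 3.10, 2.98, 2.66, 2.64 and 2.60. The largest falls by the same rule included Defa26, AY761184, Cyp3a11, Mme, Defa24 and Mptx2, with log2 changes of -3.54, -3.21, -2.86, -2.54, -2.49 and -2.49. Mme, which encodes the peptidase neprilysin, averaged 190 ± 32.3 in granuloma and 1122 ± 280 in non-granuloma libraries (adjusted p = 6.87e-05). The call of Hspa1a ended without Gr_316, Gr_359, Gr_372 or NonGr_372 (adjusted p from 0.0584 to 0.0808).

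**Figure D1:**
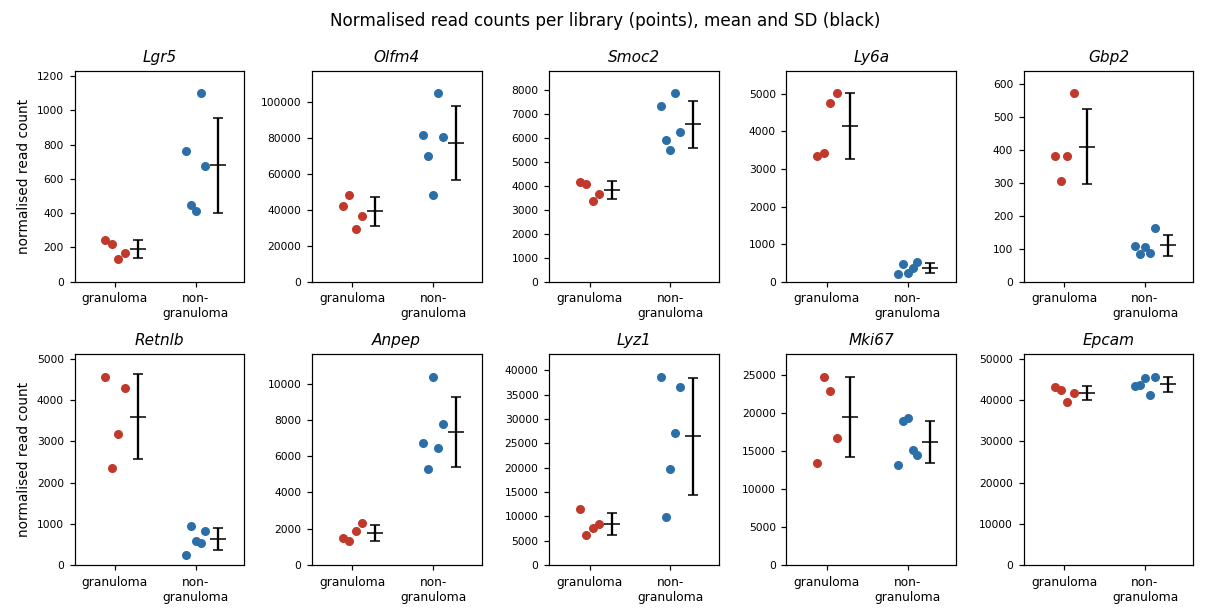
Normalised read counts (vertical axes, starting at 0) of 10 genes in the 4 granuloma (red) and 5 non-granuloma (blue) libraries, with the mean and SD in black. Every granuloma library lies below every non-granuloma library for Lgr5, Smoc2 and Anpep and above for Ly6a, Gbp2 and Retnlb. The groups overlap for Olfm4, Lyz1, Mki67 and Epcam.

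Crypt stem cell genes were lower at the granuloma as a list, with a median log2 change of -0.33 (camera, adjusted p = 3.74e-06), a call that was lost with an estimated correlation between its genes (adjusted p = 0.299). Lgr5, the receptor that marks cycling stem cells at the crypt base (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780 in the deposited coordinates, which overlap GRCm38), averaged 191 ± 50.1 in granuloma and 679 ± 277 in non-granuloma libraries, 3.40-fold lower (log2 change -1.77 ± 0.28 SE, adjusted p = 0.00217). Of the 23 genes on the stem list, 8 fell, 0 rose and 15 did not pass, and 10 fell when adjusted over the list alone. The falls included Nrn1 (log2 change -1.78, adjusted p = 0.000645), Smoc2 (-0.77, adjusted p = 0.00139) and Olfm4, a secreted stem cell glycoprotein that averaged 39205 ± 8153 against 77250 ± 20540 (adjusted p = 0.0106). Among the stem genes that did not pass, Ascl2, a stem cell transcription factor, had a log2 value of -0.70 (adjusted p = 0.215), Lrig1 of -0.13 (adjusted p = 0.439) and Prom1 of 0.10 (adjusted p = 0.595). With fry the list had an adjusted p of 0.0446. Within the Wnt target list, 1 of 10 genes tested rose (Ccnd1, log2 change 0.37) and 1 fell (Axin2, -0.73, adjusted p = 0.026), and 8 did not pass. When adjusted over the list alone, 1 rose and 6 fell. That list did not pass camera (adjusted p = 0.106; 0.00956 without NonGr_359; 0.0266 with no filter on low values; 0.639 with an estimated correlation). The Axin2 call ended without Gr_359, Gr_372, NonGr_316, NonGr_361 or NonGr_372 (adjusted p from 0.0516 to 0.0884). Ccnd1 kept its call only without Gr_316 or NonGr_336 (adjusted p from 0.0546 to 0.0844 in the other 7).

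Genes of the fetal intestinal epithelium were higher as a list, with a median of 0.73 (camera, adjusted p = 3.00e-05), a call that was lost with an estimated correlation (adjusted p = 0.121). Ly6a, also known as Sca-1 (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), averaged 4136 ± 876 in granuloma and 361.4 ± 136 in non-granuloma libraries, an 11.9-fold difference (log2 change 3.58 ± 0.26 SE, adjusted p = 6.87e-05). S100a6, a calcium-binding protein, rose by 1.69 on the log2 scale (adjusted p = 0.000372), and Krt7, a keratin, by 0.36 (adjusted p = 0.0488), a call that held only without Gr_336 (adjusted p from 0.065 to 0.14 without each of the other 8 libraries). The list thus had 3 of 15 tested genes higher, 0 lower and 12 not passing, and 10 higher with 1 lower when adjusted over the list alone. Clu, a marker of regenerating crypts, averaged 156 ± 16.7 against 95.7 ± 57.9 (log2 value 0.91, adjusted p = 0.157). Of 18 tested YAP/TAZ target genes, 2 rose (Areg, an EGF-receptor ligand, by 2.20, and Cyr61 by 1.00), 1 fell (Crim1, -0.69) and 15 did not pass, against 5 higher and 1 lower when adjusted over the list alone. The list did not pass camera (adjusted p = 0.406; 0.717 with an estimated correlation), and the Cyr61 call was lost in 7 of the 9 leave-one-out fits (adjusted p from 0.0618 to 0.0881), holding only without NonGr_316 or NonGr_359.

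Of 26 interferon-gamma response genes, 20 rose, 0 fell and 6 did not pass, and 21 rose when adjusted over the list alone. The list median was 1.64 (camera, adjusted p = 3.09e-23; adjusted p = 0.0607 with an estimated correlation). Igtp and Irgm1, immunity-related GTPases, rose by 1.94 and 0.82 on the log2 scale, and Socs1, a feedback inhibitor of cytokine signalling, by 2.70 (adjusted p = 0.000147 for each). Gbp2, a guanylate-binding protein, averaged 411 ± 114 against 110 ± 31.6 (adjusted p = 0.000492). Irf1 had a log2 value of 0.14 (adjusted p = 0.713). Among 25 tested type I interferon response genes, 20 rose, 0 fell and 5 did not pass (22 higher when adjusted over the list alone), including Isg15 (log2 change 2.04, adjusted p = 0.000365), Oasl1 (1.28) and Stat2 (1.05), with a median of 1.05 (camera, adjusted p = 3.11e-19; adjusted p = 0.0883 with an estimated correlation). Of 18 antigen processing and presentation genes, 15 rose, 0 fell and 3 did not pass, and 18 rose when adjusted over the list alone. That list had a median of 0.86 (camera, adjusted p = 8.35e-19; adjusted p = 0.119 with an estimated correlation). The genes that rose included the MHC class II genes H2-Aa (log2 change 1.30, adjusted p = 0.000384) and Cd74 (1.08, adjusted p = 0.000494) and the immunoproteasome gene Psmb8 (0.94).

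**Figure D2:**
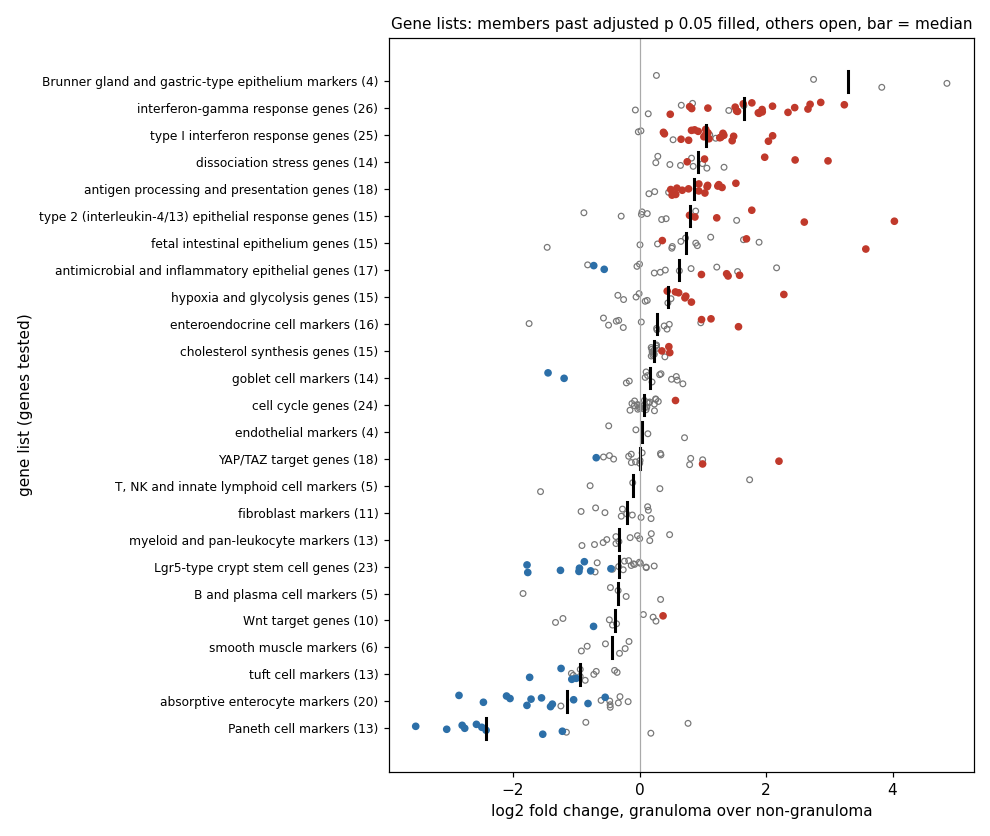
Log2 fold change of granuloma over non-granuloma libraries (horizontal axis) for the tested genes of the 25 lists that could be tested (vertical axis, with the number of genes), where filled points passed an adjusted p of 0.05, open points did not, and bars are list medians. Interferon-gamma response genes have a median of 1.64 and Paneth cell markers of -2.43.

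Of 15 tested type 2 response genes, 6 rose, 0 fell and 9 did not pass (7 higher when adjusted over the list alone). Retnlb averaged 3597 ± 1026 against 630 ± 276 (log2 change 2.60, adjusted p = 0.000764), Sprr2a3 rose by 1.22 and Pla2g4c by 0.88, with a list median of 0.79 (camera, adjusted p = 7.85e-06; adjusted p = 0.0607 with an estimated correlation). Of 13 tuft cell markers, 4 fell, 0 rose and 9 did not pass, and 10 fell when adjusted over the list alone. The tuft list median was -0.94 (camera, adjusted p = 7.86e-07; adjusted p = 0.215 with an estimated correlation). Pou2f3, the tuft cell transcription factor, averaged 127 ± 25 against 255 ± 46.1 (adjusted p = 0.00591), with falls also in Rgs13 (-1.24) and the taste-signalling channel Trpm5 (-1.07). Dclk1, a common tuft marker, had a log2 value of -0.86 (adjusted p = 0.105; 0.000839 with the replicate block and 0.0444 without Gr_336). The Rgs13 call ended without Gr_372 (adjusted p = 0.057) and the Trpm5 call without Gr_359 (adjusted p = 0.0656). Among 14 tested goblet cell markers 2 fell (Ccl6, -1.45, and Zg16, -1.19), 0 rose and 12 did not pass (3 higher and 2 lower when adjusted over the list alone), and Muc2, the main secreted mucin, had a log2 value of 0.68 (adjusted p = 0.137; 0.0259 with the replicate block and 0.0412 without Gr_336). The goblet list did not pass camera (adjusted p = 0.333; 0.802 with an estimated correlation), but did with the replicate block (adjusted p = 0.0298) and without NonGr_361 (adjusted p = 0.0425). Ccl6 and Zg16 each lost the call in 6 of the 9 leave-one-out fits (adjusted p from 0.0501 to 0.0861 and from 0.0638 to 0.0923), Ccl6 keeping it without Gr_372, NonGr_336 or NonGr_361 and Zg16 without Gr_316, NonGr_316 or NonGr_336. Of 16 enteroendocrine genes, 3 rose (the hormone genes Gcg, Tac1 and Ghrl, by 1.56, 1.13 and 0.98), 0 fell and 13 did not pass (3 higher and 1 lower when adjusted over the list alone), with no pass in camera (adjusted p = 0.218; 0.043 without NonGr_372; 0.781 with an estimated correlation). Gip, another gut hormone, had a log2 value of -1.75 (adjusted p = 0.0631; 0.000808 with the replicate block and 0.0391 without NonGr_316).

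Of 13 tested Paneth cell markers, 9 fell, 0 rose and 4 did not pass (1 higher and 11 lower when adjusted over the list alone), with a median of -2.43 (camera, adjusted p = 1.23e-07; adjusted p = 0.284 with an estimated correlation). Defa26, an antimicrobial defensin (ENSMUSG00000060070, chromosome 8, 21618183 to 21618972), averaged 39 ± 30 against 471 ± 269 (log2 change -3.54 ± 0.53 SE, adjusted p = 0.00179), and Defa24 4846 ± 1838 against 30099 ± 15243. Defensin genes have near-identical copies between which reads may be split, so single defensin values are uncertain. Lyz1, the Paneth cell lysozyme, fell by 1.53 on the log2 scale (adjusted p = 0.0152), a call that ended without Gr_359 (adjusted p = 0.0504). Itln1 had a log2 value of -1.16 (adjusted p = 0.057; 0.000601 with the replicate block, and from 0.00705 to 0.0426 without Gr_316 or NonGr_336) and Mmp7, the protease that activates defensins, of 0.18 (adjusted p = 0.77). Among 20 absorptive enterocyte markers, 12 fell, 0 rose and 8 did not pass (15 lower when adjusted over the list alone), including the brush-border peptidases Anpep (1767 ± 446 against 7328 ± 1920, adjusted p = 0.000152) and Enpep (log2 change -2.10) and the fatty-acid carrier Fabp1 (-1.38). That list had a median of -1.14 (camera, adjusted p = 1.52e-13; adjusted p = 0.134 with an estimated correlation). Of 17 tested antimicrobial and inflammatory genes, 4 rose and 2 fell, 11 did not pass, and 5 rose and 3 fell when adjusted over the list alone. The rises included Duox2 and Duoxa2, which form a hydrogen peroxide-producing oxidase (0.98 and 1.38), and the falls Pigr, the carrier of IgA across the epithelium (-0.56, adjusted p = 0.021; 0.0789 without Gr_372). The list did not pass camera (adjusted p = 0.106, and 0.505 with an estimated correlation). In camera it passed without NonGr_336 (adjusted p = 0.0449) and with no filter on low values (0.0499). Lcn2 and Cxcl5 of this list were highest in NonGr_336 (6353 and 1073). They were lowest in Gr_372, NonGr_361 and NonGr_372 (at most 120 and 37.5).

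Most cell cycle genes did not pass the test. Rrm2, a subunit of ribonucleotide reductase, was the 1 of 24 that rose (log2 change 0.56, adjusted p = 0.000451; 1 higher when adjusted over the list alone), 23 did not pass, and Mki67 averaged 19397 ± 5268 against 16187 ± 2781 (adjusted p = 0.451). The list median was 0.08 (camera, adjusted p = 0.0743; 0.0333 with the replicate block; 0.0285 without Gr_359; 0.0257 with no filter on low values; 0.444 with an estimated correlation). The exact permutation test of library scores gave an adjusted p of 0.022. Of 15 cholesterol synthesis genes, 3 rose, 0 fell and 12 did not pass (4 higher when adjusted over the list alone): Fdps by 0.48, Mvd by 0.46 and Lss by 0.35 (median 0.23; camera, adjusted p = 9.51e-06; adjusted p = 0.215 with an estimated correlation). The Mvd call ended without Gr_316, Gr_359, Gr_372, NonGr_316 or NonGr_361 (adjusted p from 0.0504 to 0.0923), and the Lss call without any 1 granuloma library or without NonGr_316, NonGr_361 or NonGr_372 (from 0.0519 to 0.114). Hypoxia and glycolysis genes included 7 of 15 that rose, 0 that fell and 8 that did not pass (8 higher and 1 lower when adjusted over the list alone). Adm, a vasodilator peptide, rose by 2.28, the glucose transporter Slc2a1 by 0.82 and the glycolytic enzyme Eno1 by 0.57 (list median 0.45; camera, adjusted p = 0.000184; adjusted p = 0.121 with an estimated correlation). Dissociation stress genes, which respond to tissue handling, had 5 of 14 higher, 0 lower and 9 not passing (5 higher when adjusted over the list alone), with a median of 0.92 (camera, adjusted p = 4.31e-05; adjusted p = 0.414 with an estimated correlation; fry, adjusted p = 0.144). NonGr_316 stood apart from its group with the highest stress list score of the 9 libraries (mean log2 value 11.9, against 11.3 to 11.8 in granuloma and 9.22 to 10.7 in the other non-granuloma libraries), and without it 8 of the 14 genes rose. Hspa1a, Hspa1b and Dusp1 rose by 2.98, 2.46 and 1.98 on the log2 scale. Dusp1 lost its call without any 1 granuloma library or without NonGr_359 or NonGr_361 (adjusted p from 0.0555 to 0.0761), and Hspa1b without any 1 granuloma library or without NonGr_336, NonGr_359 or NonGr_372 (from 0.0647 to 0.104).

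The sort genes and markers of other cell types were measured in the same libraries. Epcam averaged 41741 ± 1650.1 against 43874 ± 1839.8 (adjusted p = 0.557) and Cd44 7359 ± 628 against 6419.9 ± 1575 (adjusted p = 0.387, and 0.0265 with the replicate block). Ptprc, which encodes CD45, averaged 88.3 ± 105 against 145 ± 130 (adjusted p = 0.606). It was 242, 312 and 255 in Gr_372, NonGr_361 and NonGr_372, against 8.53 to 85.6 in the other 6 libraries. No gene passed on the lists for T and innate lymphoid cells (5 tested), B and plasma cells (5), myeloid cells (13), fibroblasts (11), smooth muscle (6) and endothelium (4), with camera adjusted p of 0.861, 0.674, 0.536, 0.674, 0.405 and 0.818 and, with an estimated correlation, 0.883, 0.785, 0.873, 0.873, 0.781 and 0.873. The count adjusted over the list alone was 0 for each of these lists. With the replicate block the myeloid marker Itgam was lower (log2 change -0.56, adjusted p = 0.0232). The myeloid list passed camera as lower without Gr_372 (adjusted p = 0.0407). Its score was 7.82 in Gr_372, 7.91 in NonGr_361 and 7.94 in NonGr_372, against 3.09 to 5.63 in the other 6 libraries. Without Gr_372 the libraries with a high score were all non-granuloma, so this call cannot be told apart from that split of the libraries. Brunner gland and gastric-type markers, of duodenal submucosal glands, had a median of 3.29 over 4 tested genes, of which 0 passed and 3 were higher when adjusted over the list alone (camera, adjusted p = 0.0405; adjusted p = 0.162 with an estimated correlation). The list lost its call without any 1 granuloma library or without NonGr_316 or NonGr_361 (adjusted p from 0.0635 to 0.205). Muc6 ranged from 520 to 2496 in granuloma libraries and from 8.84 to 1461 in non-granuloma libraries (adjusted p = 0.112; 0.0305 with the replicate block, and from 0.0307 to 0.049 without NonGr_359 or NonGr_372). The enteric glia, pancreatic and red cell lists had too few tested genes for a list test.

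**Figure D3:**
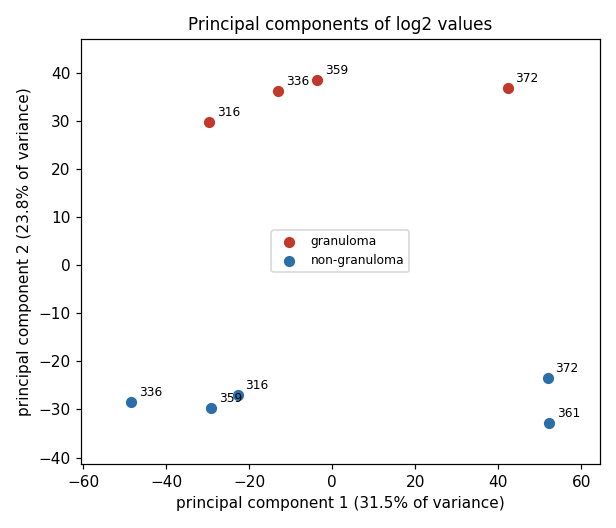
Principal components of the log2 values of the tested genes, with each library's number beside its point. Component 2 (23.8% of variance, vertical axis) separates granuloma (red) from non-granuloma (blue) libraries, and component 1 (31.5%, horizontal axis) separates Gr_372, NonGr_361 and NonGr_372 from the other 6.

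Gr_372, NonGr_361 and NonGr_372 stood apart from the other 6 libraries along the first principal component. Among those other 6, 241 genes were higher and 310 lower at the granuloma, and among these 3, 166 and 144. The fit of these 3 holds 1 granuloma library, which was assumed to vary like NonGr_361 and NonGr_372, the only source of its spread. With the replicate number as a block, in the 8 libraries whose numbers occur in both groups, 1070 genes were higher and 1100 lower. Without Gr_359 804 genes were called in all, and without Gr_372 786. A term for the set of 3 gave 779 and 839. Every main call that could be tested kept its sign in each of these fits. The authors' deposited table called 905 genes, 439 higher and 466 lower, at an adjusted p below 0.05. Of the 895 of these tested here, 875 were also called here, each in the same direction, and 503 genes were called here alone.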

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

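Several tests were chosen after the values behind them had been seen. Some asked why macrophage-type genes in Gr_372, NonGr_361 and NonGr_372, and genes such as Igfbp5 in the others, split the libraries. Others took gastric-type genes per Muc6, the libraries with Muc6 against those without it, the summed defensins and the other Paneth markers. The term for the set Gr_372, NonGr_361 and NonGr_372 was also chosen then. The splits of the libraries and the first test of the Brunner gland genes were set before.

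In 8 of 296 measures (a gene, list score or library measure within 1 group), 1 library lay far from the others of its group by Dixon's test on the log2 scale, where chance gives about 14.8. In Gr_316, Hspa1a was 5249 (others 2218 to 2493), Mptx2 1070 (430.7 to 459.4) and Irgm1 4422 (5167 to 5250). In Gr_372, Top2a was 15000 (17460 to 17740), Duox2 13070 (11490 to 11560) and Pigr 64700 (76570 to 78090). Tagln was 433.2 in NonGr_316 (101.3 to 148.4 in the others), and the cell cycle list score was 12.27 in NonGr_359 (12.39 to 12.4 in the others).

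Among 100 of the 126 possible splits of the 9 libraries into 4 and 5, 1 split, the real one, gave as many called genes (1378; highest other 249), as many higher genes (652; highest other 174; 1 split) and as many lower genes (726; highest other 75; 1 split). If the libraries are taken as unpaired, this argues against chance division for these counts. The highest other split set the 4 non-granuloma libraries whose numbers also occur in granuloma against the rest, and among the 16 splits that part all 4 shared numbers it was the only other one with any call. Those 16 are too few for a share under 0.05, so chance is not excluded with the numbers taken as pairs.

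Gr_372, NonGr_361 and NonGr_372 carried macrophage genes that the other 6 nearly lacked, although CD45-positive cells had been sorted out: Mpeg1 ranged from 1780 to 2948 against 18.1 to 71.3 and Csf1r from 504 to 792 against 0 to 37.9, while the other 6 carried Igfbp5 (487 to 10855 against 5.35 to 12.6). Xist, transcribed only from an inactive X chromosome, was 13.2 times as high on average in those 3 libraries although the Y-linked gene Ddx3y was at 1434 or more in each of the 9, which, if the mice were male (the labels give no sex), argues against their own macrophages as the source of both Xist and the macrophage genes. RNA of an outside source mixed into each set stays open. The spread of log2 ratios between libraries over that of counting error was 2.001 for 8 macrophage-type genes. It was 2.36 for 6 genes, among them Igfbp5 and Krt14, picked as high in NonGr_316, NonGr_336 and NonGr_359 against NonGr_361 and NonGr_372. The tissue of origin of these 6 genes was not tested. A spread between single libraries cannot exclude a shared source. With a term for the split, 97.5% of the granuloma calls held. But the set holds libraries of both groups, and of the 8 and the 6 genes above 0 were called. Few calls could therefore have ended, so this decides little on whether the split accounts for the granuloma calls. Apart from these macrophages, no biological explanation of the split was tested.

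Brunner gland genes were present in 4 of 4 granuloma libraries and in NonGr_359 and NonGr_372 (Muc6 1461 and 982), and low in NonGr_316, NonGr_336 and NonGr_361 (8.84, 10.9 and 28). Over the called genes, non-granuloma libraries with Muc6 differed from those without by a median of -4.17% of the granuloma difference, but called genes vary little within non-granuloma and no other pair exceeded 13.9%, so this test decides nothing. Over 781 genes called against the libraries without Muc6, those with Muc6 lay a median of 3.77% of the way to the granuloma level. The 2 libraries lay at -5.96% and 13.2%, and had no part in choosing these genes. For these genes, this argues against gland content, as far as Muc6 marks it, as the cause of most of the difference. Biopsy position was judged only through Muc6. With the Muc6 and Tff2 covariate 43.6% of the main calls were kept, and with only the non-granuloma libraries with Muc6 and Tff2 41.5%. All main calls tested there kept their direction, and the cause of the losses was not tested. Anxa10, Ctse, Gkn1 and Vsig1 were higher per unit of Muc6 in granuloma libraries by 9.88, 2.82, 6.69 and 2.29 times (median 4.75), against only 2 non-granuloma libraries; without Gr_316 or Gr_359 the Anxa10, Gkn1 and median ratios were 6.24, 3.51 and 2.95, and without NonGr_359, where Gkn1 was 0, the Gkn1 ratio was 3.34. The lowest granuloma library had 4.84 (Anxa10), 1.83 (Ctse) and 1.05 (Vsig1) times the level per Muc6 of the higher non-granuloma one. Gkn1 was 33.4 or less in each library. But these genes were chosen after their values had been seen, and each was higher in every granuloma library than in every non-granuloma one. Muc6 in NonGr_359 and NonGr_372 lay within its granuloma range (520 to 2496). The choice therefore favoured higher ratios in granuloma, so the test decides nothing on gland tissue alone. A change of the gland or crypt cells at the granuloma stays open as a hypothesis.

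Defensin genes of the Paneth list fell more, on average, than the Paneth markers Lyz1, Itln1, Mmp7 and Pnliprp2. Reads divided differently among near-identical defensin copies would leave their sum level, but the sum over 30 defensin genes was 5.71-fold lower at the granuloma (log2 change -2.51; exact permutation p = 0.0159), which argues against it. The 7 tested defensins of the Paneth list fell by 1.88 more on the log2 scale than Lyz1, Itln1, Mmp7 and Pnliprp2 (exact permutation p = 0.00794, the smallest possible). The changes were -2.81 and -0.93. For these markers, this argues against fewer Paneth cells as the whole cause. It depends on the markers taken: Mmp7 changed by 0.18, while Mptx2, outside the Paneth list, changed by -2.49, as did Defa24 (-2.49). Lower defensin expression within Paneth cells may contribute, a hypothesis that arose from these libraries and was not itself tested. A smaller share of Paneth cells stays open as part of the change. Both p-values take the libraries as unpaired: within the 4 pairs the sum and the excess fell in 4 of 4 (mean differences of -2.48 ± 0.81 and -1.82 ± 0.36, SD), where the smallest possible exact p is 0.125.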

How the results depend on the processing

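The added settings named in the processing summary were chosen after the data had been seen. All main calls that could be tested kept their direction in each setting. With the replicate block, 1070 genes were higher and 1100 lower, and with edgeR, TMM and the block, 1104 were lower. DESeq2 called 1010 higher genes. Leaving out 1 library gave 330 to 821 higher and 443 to 782 lower genes; without Gr_359 804 genes were called in all, and without Gr_372 786. With fewer libraries, the higher and lower genes numbered 241 and 310 without Gr_372, NonGr_361 and NonGr_372, 166 and 144 with these 3 alone (1 granuloma library, assumed to vary like the 2 others), and 284 and 370 with only the non-granuloma libraries with Muc6 and Tff2. The Muc6 and Tff2 covariate gave 270 and 393; the cause was not tested. With an estimated correlation the stem, fetal and interferon-gamma lists no longer passed camera (adjusted p = 0.299, 0.121 and 0.0607), nor did the other 10 lists that had passed; the estimated correlation exceeded the preset 0.01 in 12 of these 13 lists, all but the Brunner list. The fibroblast list, which had not passed, turned to higher with only the non-granuloma libraries with Muc6 and Tff2 (adjusted p = 0.0376); the cause was not tested. Without a low-value filter the Wnt, cell cycle and antimicrobial lists came to pass (adjusted p = 0.0266, 0.0257 and 0.0499), as did the Wnt list in those 3 libraries alone (0.0134), the goblet and cell cycle lists in the other 6 (0.0318 for each) and with edgeR, TMM and the block (0.0306 and 0.0402), and the cell cycle list with the covariate (0.0161) and with only the non-granuloma libraries with Muc6 and Tff2 (0.0257). The Brunner list also lost its call in 16 of 22 other settings (adjusted p from 0.0577 to 0.263). With the block 15 named genes and the goblet and cell cycle lists came to pass. Among these genes Dock5, Wwc1, Cxcl10 and Agr2 were higher and Avil, Mttp and Rbp2 lower. The block changed no other call of a named gene or list, and over all genes 1300 of the 1371 main calls tested there were kept. The block fit also leaves out NonGr_361. Without that library alone, the goblet list (camera, adjusted p = 0.0425) and Agr2 already passed. Agr2 had an adjusted p from 0.0139 to 0.0154 without Gr_336 or NonGr_361. On simulated reads at this depth and number of libraries, 34.3% of 1.5-fold changes were recovered.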

Other observations

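Gene families, grouped by symbol after the data had been seen, gave further biology. Of 159 families with at least 10 tested members, each tested for higher and for lower genes, detoxifying enzymes stood out among the lower genes. Of 36 cytochrome P450 (Cyp) genes, 17 were lower (Fisher's exact test, adjusted p = 4.55e-11), as were 10 of 12 carboxylesterases (Ces; adjusted p = 6.70e-10) and 7 of 10 UDP-glucuronosyltransferases (Ugt; adjusted p = 5.25e-06). Ces2a averaged 512 ± 23.7 in granuloma and 1511 ± 409 in non-granuloma libraries (n = 4 and 5), a log2 change of -1.52, and Ugt2b5 changed by -1.88. Absorptive enterocyte markers, which include Cyp3a11, moved with these families (12 of 20 lower, list median -1.14). Solute carriers (Slc) went both ways (median log2 change -0.10), with 38 of 267 genes lower (adjusted p = 2.59e-07) and 21 higher (adjusted p = 0.217). The lower ones included the peptide transporter Slc15a1 (-1.29) and the amino acid transporter Slc6a19 (-1.41; its call ended without Gr_316, Gr_336 or NonGr_359, with adjusted p from 0.0506 to 0.0577). Of 12 hydroxysteroid dehydrogenases (Hsd), 5 were lower (adjusted p = 0.0102). Mitochondrial ribosomal proteins of the large subunit (Mrpl) were higher for 9 of 49 genes (adjusted p = 0.0124), and those of the small subunit (Mrps) for 1 of 29 (adjusted p = 1). Genes of a family are not independent, so these p-values are too small, and the example genes were chosen after their values had been seen.

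Among genes outside the fixed lists and chosen after their values were seen, Alox15, a lipoxygenase, averaged 289 ± 66.5 in granuloma and 46.8 ± 35 in non-granuloma libraries (log2 change 2.94, adjusted p = 0.00333). Il1b, a cytokine of myeloid cells, averaged 80.1 ± 74.7 against 6.4 ± 7.06 (adjusted p = 0.0296), and Srgn, a proteoglycan of blood cells, 158 ± 119 against 34 ± 13.2 (adjusted p = 0.00982). Gr_372, which carried macrophage genes (Mpeg1 at 1779.8), was the highest for both. Without it Il1b averaged 50.8 (adjusted p = 0.105) and Srgn 98.5 (adjusted p = 0.0226). NonGr_361 and NonGr_372 had more Mpeg1 (2948 and 2713), but Il1b of 7 and 18.4 and Srgn of 39.2 and 52.7. In Gr_359, Il1b was 116 with Mpeg1 at 71.3. The source of these transcripts was not tested. The Il1b call also ended without Gr_359, NonGr_316, NonGr_336 or NonGr_359 (adjusted p from 0.056 to 0.106). Il33, an alarmin on the type 2 list, averaged 259 ± 20.3 against 79 ± 28.7 (adjusted p = 0.0011).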
